A study of Mus musculus with 30 samples.

How the data were processed

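RNA of the quadriceps muscle of male C57BL/6J mice (the labels spell the strain C56BL/6J) was measured on Affymetrix arrays with biotin labelling, 1 mouse per array. There were 30 arrays in 3 groups of 10: mice killed at day 0 after a 3-week low fat run-in (LF day 0, 12 weeks old), mice kept on the low fat diet for 56 days (LF day 56, 20 weeks old) and mice fed a high fat diet for 56 days (HF day 56, 20 weeks old). After the run-in, mice were assigned to the diets at random. Groups were taken from the labels. Replicate numbers recur in the 3 groups but the labels give every mouse its own number, so arrays were not paired.

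The deposited table holds 1 linear expression intensity per gene and array, made by the authors with GCRMA according to the submitters' processing notes, which state no version. The values ran from 1.2 to 30599, were given in steps of 0.1, and had array medians between 8.9 and 9.4, so the values were read as linear and on a common scale. The log2 of each intensity was taken with a pseudocount of 0. Of 16539 entries, 64 control probe sets were left out, and the other 16475 were tested. A single gene symbol was given for 15780 of them, none was given for 695, and no gene had several entries. Gene numbers matched the reference names for 15752 entries, and 0 symbols changed. Entries without a symbol were tested and counted but not named. Genome coordinates were not used here. For arrays, the number of mice limits the precision, and signal near background limits what can be seen: 6844 entries exceeded an intensity of 20 on at least 5 arrays and 9631 did not.

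Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, not robust, group as the only factor, all 30 arrays in 1 fit, 27 residual and 3.97 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over all 16475 entries in each comparison, with a threshold of 0.05. Standard errors (SE) are those of the fit, and SD is between arrays. For each gene, the number of arrays on the stated side of the other group's mean is given out of 10. Counts are also given for changes of at least 1.5-fold. In all, 35 gene lists (21 pathways and 14 cell types, 712 symbols, 599 of them measured) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were alternatives. Members past the test were counted over all genes and adjusted over the list alone. Mean list levels per array used members above an intensity of 20 on at least 5 arrays.

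The comparisons, their tests, the lists, the rule for named genes and a first group of alternative settings were fixed before the data were examined. The rule named, in each comparison, the 10 largest rises and 10 largest falls among genes past the threshold. Where fewer than 5 genes passed, it added the 10 genes of smallest p among those that did not. It also took up to 4 members of smallest p from each list that passed and, for the diet comparison, 18 genes of fat, glucose and adipokine metabolism, of which 17 were measured (Irs1 was not). The overlap of calls against the shared LF day 0 arrays was set beside the overlap of independent lists, 100 simulations with unchanged groups, and 100 splits of the LF day 0 arrays into 2 groups of 5. The within-group spread at day 56 was compared by a two-sided permutation test of 100000 resamples with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.

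That first group held a fit of only the groups compared, trend and robust priors, array weights, quantile normalization, median centring, filters on low or flat entries, the replicate number as a block, adjacent mouse numbers as a random block, slow fibre and adipocyte scores as covariates, another threshold, and leaving out each array. Other alternatives were added only after the data had been examined. Arrays were parted into 2 sets (21 and 9) at the widest gap in the 5' to 3' signal of spike-in control RNAs. That signal was the mean over 4 pairs of probe sets for the control RNAs dap and thr. Earlier versions of these sets, by clustering into 3 sets and by the level of Hdlbp, were tried first and replaced by the gap. The set served as a block, its index as a covariate, and each set was fitted alone. A neutrophil score was used as a covariate, alone and with the set and slow fibre score, and arrays with S100a8 above an intensity of 100 were left out. Differences in group means of named genes were also taken without each array in turn. Members shared with the mitochondrial fatty acid oxidation list were also left out of the list of PPAR target genes. Small lists of granulocyte precursor, red cell precursor, mature neutrophil and adipocyte-restricted genes were likewise chosen after the data had been examined. The test of labelling for the fatty acid oxidation genes first used their median with the set as a block, which evenly spread sets cannot move, and was replaced by the medians within each set. With evenly spread sets the pooled differences are weighted means of those within the sets, so these medians are no separate test either. The test of slower fibres first used the list with the slow fibre score as a covariate, which equal scores cannot move, and was replaced by the score difference that the slope within groups would need. The test of blood first used the highest Mpo with the correlations of Csf3r and Cxcr2, and was replaced by the arrays with Mpo above and under an intensity of 20. The test of Lep was first read as excluding more adipocytes and then left open, because Lep lay near background in LF day 56.

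The diet test was also tested on simulated data made from the residuals of all 30 arrays, shuffled over the groups. In each of 20 draws 200 genes were changed, taken from the 6844 entries above an intensity of 20 on at least 5 arrays. The test recovered 51.3% of such genes changed 1.25-fold, 88.6% of those changed 1.5-fold and 98.0% of those changed 2-fold. It gave a median of 2.5, 7 and 5.5 false calls and at most 95, 246 and 37. Recovery among entries of lower signal was not tested. A list shifted by 0.2 on the log2 scale passed in 20 of 20 draws with the preset correlation, 16 with an estimated correlation and 18 with fry. A median of 6, 0 and 0 other lists passed alongside it, and at most 14, 1 and 3.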

Results

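The data were 30 quadriceps muscle arrays from male mice, 10 at day 0 of the diet intervention (LF day 0), 10 after 56 days on the low fat diet (LF day 56) and 10 after 56 days on a high fat diet (HF day 56). Each array showed between 6334 and 6563 entries above an intensity of 20. Arrays of a group correlated with one another at a median r of 0.990 to 0.994 across genes, which are not independent replicates. The series was set up to ask how muscle gene expression responds to a high fat diet that leads to obesity and insulin resistance.

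The arrays fell into 2 sets that the groups did not explain. On 9 arrays, 3 of each group, the spike-in control RNAs had a higher 5' to 3' signal than on the other 21, and Jph2, a protein of the muscle triad junction, read 9.64 ± 0.14 (log2, SD, n = 9) against 6.74 ± 0.42 (SD, n = 21). Between these sets 3660 genes differed in limma (1717 higher and 1943 lower on the 9 arrays), and Ucp3, a mitochondrial carrier of muscle, differed by 1.02. The sets were spread evenly over the groups, and values within each set are given below beside some of the pooled ones. On 17 arrays, 7 of LF day 0, 4 of LF day 56 and 6 of HF day 56, the neutrophil gene S100a8 lay above an intensity of 100. Within the set of 9 arrays S100a8 was not spread evenly. It read 9.59, 10.99 and 11.79 (log2) in LF day 0, 3.02, 2.63 and 2.87 in LF day 56, and 2.70, 9.94 and 9.19 in HF day 56. Differences between groups within the 9 arrays therefore cannot be told apart from a difference in S100a8 level. Myh7, the slow myosin heavy chain, ranged from 1.68 to 9.72 (log2) over the 30 arrays.

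**Figure D1:**
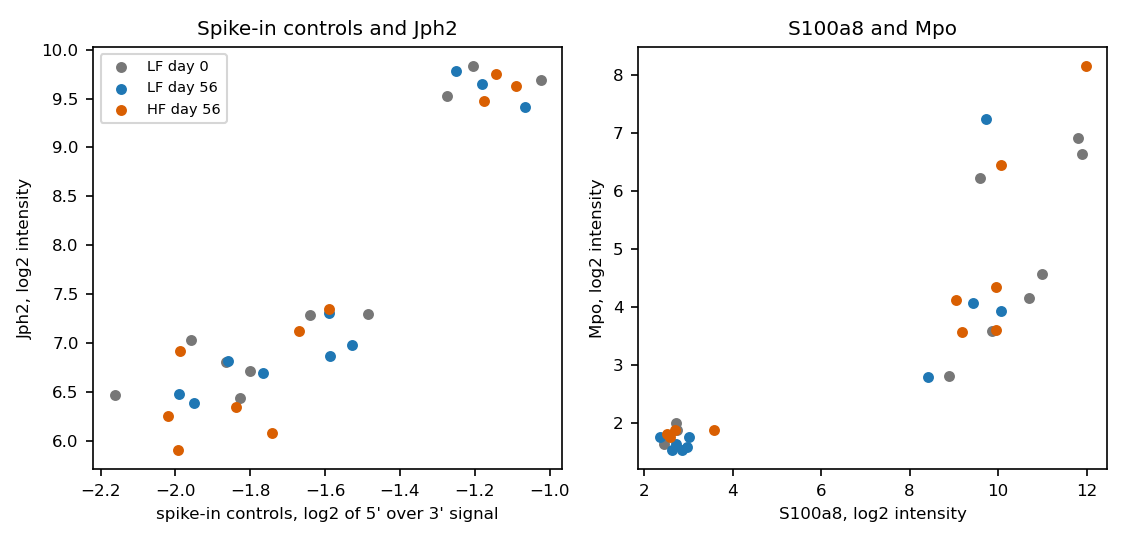
Each point is 1 of the 30 arrays, coloured by group; the left panel plots Jph2 (log2 intensity) against the spike-in controls' log2 ratio of 5' over 3' signal, and the right panel Mpo against S100a8 (both log2 intensity). The 9 arrays with a spike-in ratio of -1.27 or above have Jph2 at 9.41 or higher, and Mpo stays at or below 2.0 on the 13 arrays with low S100a8.

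The comparison of HF day 56 with LF day 56 asks what the diet changed at equal age. A few genes of fatty acid breakdown rose on the high fat diet. Decr1, a reductase that lets mitochondria degrade unsaturated fatty acids, rose by 0.38 ± 0.06 (log2, SE; adjusted p = 0.00954). Ech1, an isomerase that also acts on unsaturated fatty acids, rose by 0.41 ± 0.08 (adjusted p = 0.0383), and Eci2, another enoyl-CoA isomerase, by 0.21 ± 0.04 (adjusted p = 0.0383). Among the genes that passed, the largest rise was that of BC048679, by 1.02 ± 0.16 (adjusted p = 0.00435), from 7.59 ± 0.44 to 8.60 ± 0.39 (SD). For each of these 4 genes, 10 of 10 HF arrays lay above the LF mean.

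These 4 genes, all higher, were the only ones of 16475 to pass in limma, and 1 of them changed at least 1.5-fold. At an unadjusted p below 0.05 there were 841 genes, where chance gives 824, and at p below 0.01 there were 213, where chance gives 165. Within the sets of 21 and 9 arrays the differences were 0.86 and 1.39 for BC048679, 0.33 and 0.48 for Decr1, 0.37 and 0.50 for Ech1, and 0.19 and 0.25 for Eci2. With the set as a block, 6 genes passed, and in limma fits of each set alone 0 passed (835 and 782 at an unadjusted p below 0.05). BC048679 and Decr1 passed in 20 of 20 fits with 1 array left out, Ech1 in 8 and Eci2 in 6 (highest adjusted p 0.109 for both). In a limma fit of only the groups compared 0 genes passed, and with quantile normalization Eci2 did not (limma, adjusted p = 0.074). Leaving out 1 array gave 2 genes without replicate 1, 2, 3, 5, 6, 7, 9 or 10 of LF day 56 or replicate 2, 4, 6 or 8 of HF day 56, and 15, 10, 8 and 11 genes without replicates 3, 5, 7 and 9 of HF day 56.

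**Figure D2:**
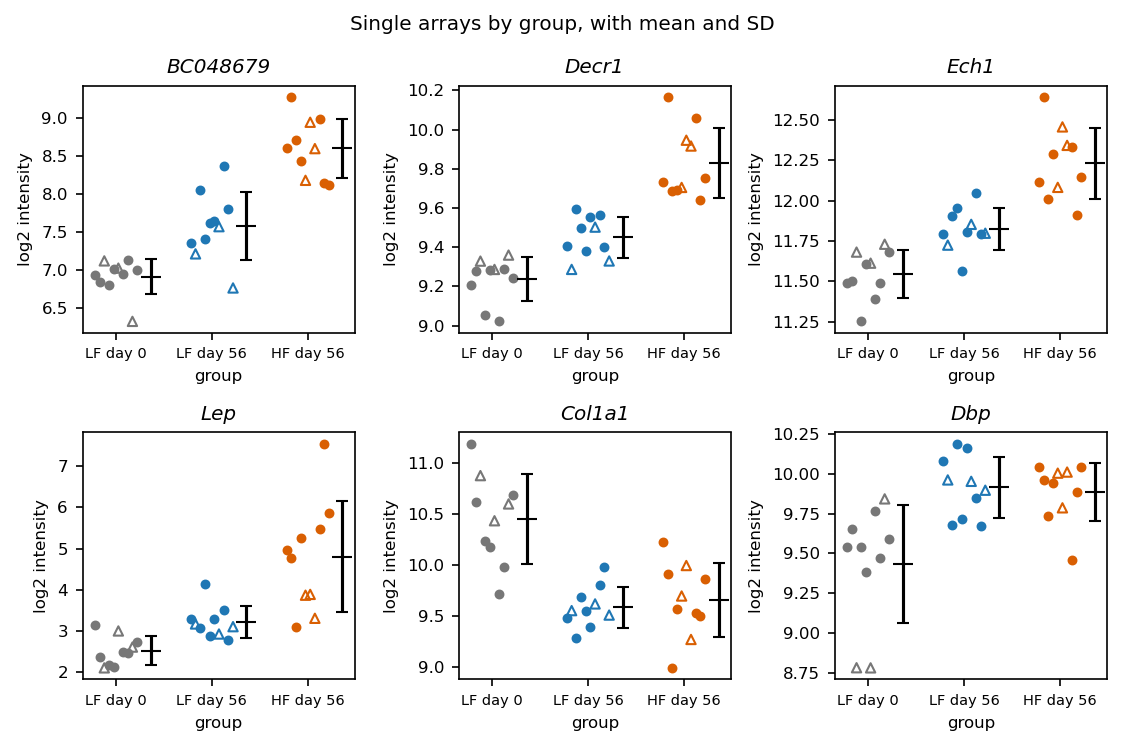
Log2 intensity of 6 genes on single arrays by group, with the mean and SD in black; filled circles are the 21 arrays of lower spike-in ratio and open triangles the other 9. BC048679, Decr1 and Ech1 lie higher in HF day 56 than in LF day 56, and Col1a1 lies lower at day 56 than at day 0 on both diets.

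The mitochondrial fatty acid oxidation list rose on the high fat diet, by a median of 0.17 (adjusted p = 3.55e-20, and 0.0284 with an estimated correlation), with 21 of its 23 measured genes higher and 2 lower. Of these, 2 passed over all genes and 11 when adjusted over the list alone, and 9 of 10 HF arrays had a list mean above that of LF (10.1 ± 0.140 against 9.97 ± 0.0680, SD). Acadl (0.26 ± 0.06, adjusted p = 0.123), a long-chain acyl-CoA dehydrogenase, and Cpt2 (0.30 ± 0.07, adjusted p = 0.196), which completes the entry of fatty acids into mitochondria, did not pass alone. The median was 0.15 within the 21 arrays (adjusted p = 1.89e-11) and 0.23 within the 9 (adjusted p = 7.23e-13), both with the preset correlation only. PPAR target genes rose as well: 23 measured, median 0.23, adjusted p = 4.10e-11, and 0.0284 with an estimated correlation. Over all genes 2 of them passed (Decr1 and Ech1), and over the list alone 9 were higher and 1 lower. Among its members, Cd36, a fatty acid transporter, differed by 0.31 ± 0.07 (adjusted p = 0.102) and Plin5, a lipid droplet protein, by 0.56 ± 0.13 (adjusted p = 0.112). The list shares 6 members with mitochondrial fatty acid oxidation, and its other 17 had a median of 0.23 (adjusted p = 2.9e-06, and 0.0722 with an estimated correlation).

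The other 8 lists that passed with the preset correlation did not hold with an estimated one. Fatty acid uptake and triglyceride storage (20 genes, 4 adjusted over the list alone) had a median of 0.12 and an adjusted p = 2.56e-06, but adjusted p = 0.101 with an estimated correlation; Mgll and Slc27a1 differed by 0.31 and 0.39 (both adjusted p = 0.542). Collagens and extracellular matrix (27 genes, 4 adjusted over the list alone) had a median of 0.14 and an adjusted p = 1.20e-06, but adjusted p = 0.408 with an estimated correlation. Its members Postn, Sparc, Col4a2 and Thbs2 differed by 0.52, 0.30, 0.24 and 0.40. Branched-chain amino acid breakdown was lower (median -0.06, adjusted p = 0.00453, and adjusted p = 0.384 with an estimated correlation), with Mccc1 at -0.17 and Ppm1k at -0.28, Dbt at -0.20 and Pcca at -0.08. So were the 9 measured ribosomal protein genes (median -0.05, adjusted p = 0.0139, and adjusted p = 0.372 with an estimated correlation), with Rps6 at -0.22, Rpl14 at -0.12, and Rpl8 and Rps14 at -0.06.

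Markers of 4 other cell types were among these 8 lists, with 0 members past the test over all genes. Neutrophil markers had a median of 1.13 (adjusted p = 0.0139, and adjusted p = 0.528 with an estimated correlation), with 6 of 10 HF arrays above the LF mean. Lcn2 differed by 1.18 ± 0.88, Camp by 1.16 ± 1.0, Mpo by 0.98 ± 0.84 and Elane by 0.53 ± 0.43. Without replicate 2 of HF day 56 these were 0.63, 0.60, 0.49 and 0.16. Mpo was 1.47 without replicate 9 of LF day 56. Adipocyte markers had a median of 0.12 (adjusted p = 0.0459, and adjusted p = 0.528 with an estimated correlation), among them Thrsp at -0.32 (-0.19 without replicate 6 of LF day 56) and Slc7a10 at 0.33 (0.18 without replicate 9 of HF day 56). Macrophage markers had a median of 0.12 (adjusted p = 0.0159, and adjusted p = 0.552 with an estimated correlation). Cd68 differed by 0.28, Cd53 by 0.41 (0.21 without replicate 2 of HF day 56), and Laptm5 and Itgam by 0.17 each (Itgam 0.11 without replicate 4 of LF day 56). These 4 genes lay under a mean intensity of 20 in both groups, as did Elane, Mpo, Slc7a10 and Cdh5, and Lcn2 and Camp did in LF, so the sizes of their differences are uncertain. Endothelial markers had a median of 0.12 (adjusted p = 0.0398, and adjusted p = 0.384 with an estimated correlation). Emcn differed by 0.26, and Cdh5, Esam and Eng by 0.16, 0.12 and 0.16 (Esam 0.07 without replicate 5 of LF day 56, Eng 0.09 without replicate 6 of HF day 56). With the adipocyte score as a covariate 3 genes passed, and Ech1 (0.39, adjusted p = 0.111) and Eci2 (0.20, adjusted p = 0.146) were not among them. With the neutrophil score 3 passed, and Eci2 (0.20, adjusted p = 0.0756) did not. Neutrophil markers and adipocyte markers did not pass within the 21 arrays (adjusted p = 0.416 and 0.225) and did within the 9 (1.97e-07 and 0.0288). On the 9, replicates 6 and 7 of HF day 56 were high in S100a8 and the LF day 56 arrays were not. Macrophage and endothelial markers passed within the 21 (0.00272 and 0.00527) and not within the 9 (0.791 and 0.574). Without the arrays with S100a8 above 100, which left 6 LF and 4 HF arrays, 0 genes passed in limma (728 at an unadjusted p below 0.05). Mitochondrial fatty acid oxidation then passed at the preset correlation with an adjusted p = 0.00223 (camera). An estimated correlation was not used on these arrays. Random regroupings of the day 56 arrays gave this list an unadjusted camera p as small as 1e-10, so the pass says little. The mean of that list ran from 9.93 to 10.11 on these 4 HF arrays and from 9.82 to 10.07 on these 6 LF arrays. On the arrays high in S100a8 it ran from 10.09 to 10.34 in HF and from 9.96 to 10.02 in LF.

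Genes of insulin action and adipokine signalling did not pass. Lep, the adipocyte hormone leptin, differed by 1.58 ± 0.35 (adjusted p = 0.0911), higher in 9 of 10 HF arrays, by 2.0 within the 21 arrays and 0.62 within the 9. Adiponectin (Adipoq) differed by 0.53 ± 0.20 (adjusted p = 0.823), and its receptors Adipor1 and Adipor2 by 0.04 and 0.02. The leptin receptor Lepr differed by 0.02, the insulin-regulated glucose transporter Slc2a4 by -0.12, Irs2 by -0.30 (adjusted p = 0.859), and the coactivator Ppargc1a by -0.23. The fat-responsive genes Pdk4, Ucp3, Angptl4 and Cpt1b differed by -0.07, -0.28, 0.35 and 0.18, and the desaturase Scd1 by -0.13. The ubiquitin ligase Fbxo32 and the cytokines Tnf and Ccl2 differed by -0.07, -0.09 and 0.08. Of the named values that did not pass in this comparison, 21 moved by over 1.5 times with 1 array left out, and Adipor2 turned below 0 without replicate 6 of LF day 56. Lepr, Irs2, Tnf and Ccl2 lay under a mean intensity of 20 in both groups (at most 8.4), and Lep did in LF (9.3). Near background neither a difference nor its absence can be read from them. Among the 25 lists that did not pass was peroxisomal fatty acid oxidation (median 0.02, adjusted p = 0.388), of which Ech1 was the only member past the test. Others were oxidative phosphorylation (adjusted p = 0.799), the tricarboxylic acid cycle (0.607), glycolysis (0.371), insulin signalling (0.970), adipokine receptors (0.388) and pro-inflammatory cytokines (0.657). So were the slow and glycolytic fibre markers (0.915 for both) and the fast type IIA and IIX fibre markers (0.368). Of the genes of smallest p that did not pass, Mlf1, Nrep and Lmod3 were lower (-0.30, -0.31 and -0.24; adjusted p = 0.0606, 0.0693 and 0.0693), in 10, 9 and 10 of 10 HF arrays. Chrna2, Retsat and Psat1 were higher (0.51, 0.33 and 0.64; each adjusted p = 0.0717), as were Slc51b (0.46, adjusted p = 0.0779), Cfb (0.42) and Npr3 (0.56; both adjusted p = 0.0911). Of the 6 higher ones, all but Retsat lay under a mean intensity of 20 in both groups, so the sizes of their differences are uncertain.

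The comparison of LF day 56 with LF day 0 shows the change over 56 days on the low fat diet, when the mice aged from 12 to 20 weeks. Age, time on the diet and the day of killing are not separable in it. Nor is the amount of bone, cartilage or tendon taken with the muscle, since marker genes of these tissues fell as well (below). Collagen and matrix genes fell, by a list median of 0.47. Whole samples were measured, so a fall within the muscle itself was not tested. The main fibrillar collagen chains Col1a1, Col1a2 and Col3a1 fell by 0.86 ± 0.15, 0.83 ± 0.13 and 0.63 ± 0.10 (log2, SE; adjusted p = 0.00112, 0.000451 and 0.000373), each on 10 of 10 arrays. The circadian clock list rose, with Dbp higher by 0.48 ± 0.11 (adjusted p = 0.0291) and Ciart by 0.85 ± 0.18 (adjusted p = 0.0138). Sln, the sarcolipin that regulates the calcium pump of the sarcoplasmic reticulum, rose by 1.54 ± 0.29 (adjusted p = 0.00398), at mean intensities of 5.5 and 16.1 that both lie under 20.

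In all 140 genes changed in limma, 37 higher and 103 lower, and 49 of them at least 1.5-fold (12 higher, 37 lower). Rises and falls are ranked only among those of them with a symbol. After Sln, the largest rises were those of Dkk3 (1.41, adjusted p = 0.000128), Tmem45b (1.27), Rasd2 (1.10), Ciart, Mfsd4a (0.74), Stab2 (0.71), Mss51 (0.70), BC048679 (0.67) and Tmem37 (0.64), each with an adjusted p of 0.0339 or below and on at least 9 of 10 arrays. The largest falls were those of the bone matrix gene Ibsp (-2.08 ± 0.49, adjusted p = 0.0312) and the cartilage collagen Col2a1 (-1.95 ± 0.45, adjusted p = 0.0234). Each of these lay above an intensity of 20 on 6 LF day 0 arrays and on 0 of LF day 56. With the neutrophil score as a covariate they were -1.23 ± 0.27 (adjusted p = 0.0241) and -1.23 ± 0.29 (adjusted p = 0.0352). The Wnt inhibitor Wif1 (-1.27), the matrix proteoglycans Kera (-1.03) and Omd (-0.96), Mettl21e (-1.0), Prnd (-0.98), tenascin C (Tnc, -0.92) and the apelin receptor Aplnr (-0.87) fell on 10 of 10 arrays as well, with adjusted p-values of 0.0102 or below. Like Sln, Prnd and Col11a1 lay under a mean intensity of 20 in both groups. Tmem45b, Ibsp, Col2a1, Wif1, Mettl21e and Omd did in 1 of them, so the sizes of these changes are uncertain.

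Of 27 measured collagen and matrix genes 13 fell over all genes and 24 when adjusted over the list alone, with a median of -0.47 (adjusted p = 1.01e-36, and 0.00523 with an estimated correlation). On 10 of 10 LF day 56 arrays the list mean lay below that of LF day 0, and Sparc (-0.56) and Col5a2 (-0.76) were among the members. Tendon markers fell too, 5 of 11 over all genes and 9 adjusted over the list alone (median -0.61, adjusted p = 8.48e-15, and 0.00523 with an estimated correlation), with Tnmd at -0.81, Col11a1 at -0.81 and Thbs4 at -0.46. The circadian clock list rose: 4 of 19 genes over all genes, 8 higher and 1 lower adjusted over the list alone (median 0.17, adjusted p = 7.70e-07, and 0.00523 with an estimated correlation), higher on 10 of 10 arrays. Its members Bhlhe40 and Cry2 rose by 0.34 and 0.31. Endothelial markers fell by a median of 0.19 (adjusted p = 8.22e-05, and 0.0321 with an estimated correlation); 1 of 14 passed, the tight junction gene Cldn5 (-0.79, adjusted p = 0.0130), beside Tie1 (-0.38), Cdh5 (-0.18) and Egfl7 (-0.22), which did not.

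**Figure D3:**
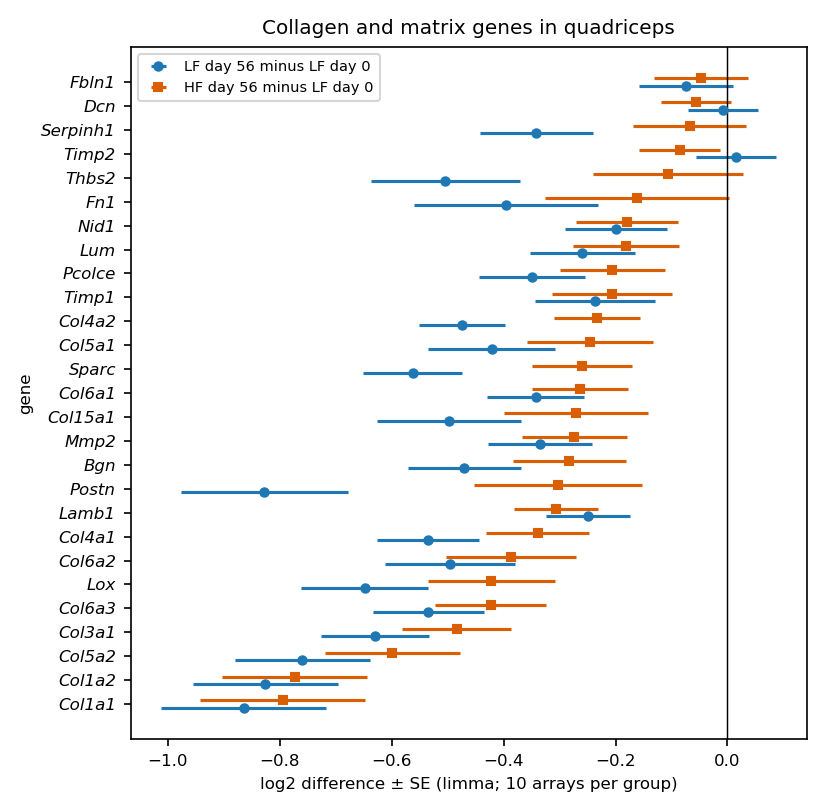
Log2 difference ± SE (limma, 10 arrays per group) of the 27 measured collagen and matrix genes, for LF day 56 (circles) and HF day 56 (squares) against LF day 0. Col1a1 lies at -0.86 in LF and -0.79 in HF, and the medians are -0.47 and -0.26.

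Of the 13 lists that passed, these 4 held with an estimated correlation and 9 did not. Mitochondrial fatty acid oxidation was higher by a median of 0.11 (adjusted p = 7.70e-07, and adjusted p = 0.274 with an estimated correlation) with 1 of 23 genes past the test, Acadm (0.23, adjusted p = 0.0142); Decr1, Eci1 and Etfdh differed by 0.22, 0.21 and 0.14. PPAR targets (adjusted p = 0.00278, Ech1 at 0.28, Fbp2 at 0.32 and Pex11a at 0.39), branched-chain amino acid breakdown (0.00306, Mccc1 and Aldh6a1 at 0.13) and ribosomal proteins (0.0341, Rpl4 at 0.11) had adjusted p = 0.274 with an estimated correlation. Fatty acid uptake and storage had an adjusted p = 0.0221 (Slc27a1 at 0.38, G0s2 and Dgat1 at 0.27), and adjusted p = 0.349 with an estimated correlation. Neuromuscular junction and denervation genes, where only Sln passed, had an adjusted p = 0.0406, adjusted p = 0.146 with an estimated correlation, and Musk differed by 0.30 (0.14 without replicate 10 of LF day 56). Adipocyte markers had a median of 0.44 (adjusted p = 2.64e-04, and adjusted p = 0.274 with an estimated correlation), with Cidec at 1.06 and Ucp1 at 1.06 (0.53 without replicate 6 of LF day 56). Neutrophil markers had a median of -2.05 (adjusted p = 1.59e-04, and adjusted p = 0.345 with an estimated correlation), with Lcn2 at -2.20 and Ltf at -2.06, and cell cycle genes -0.26 (adjusted p = 2.64e-04, and adjusted p = 0.410 with an estimated correlation), with Top2a at -0.56 (-0.31 without replicate 2 of LF day 0) and Ccna2 at -0.43. Top2a, Ccna2, Ucp1, Musk and Cdh5 lay under a mean intensity of 20 in both groups, and Lcn2, Ltf and Dgat1 did in 1 of them. Over all 30 arrays, the mean of the 4 cell cycle genes with signal followed S100a8. It was at most 3.49 (log2) on the arrays with S100a8 under 100 and at least 3.88 on those above. A change of this list over time cannot be told apart from the unequal number of arrays high in S100a8.

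With the neutrophil score as a covariate 84 genes passed, and 7 of the named genes no longer did (adjusted p between 0.0515 and 0.106). The clock genes Ciart, Cry2, Bhlhe40 and Dbp were then at 0.81, 0.29, 0.30 and 0.47, against 0.85, 0.31, 0.34 and 0.48 without the score. Mss51, Tmem45b and Col11a1 were at 0.62, 1.27 and -0.70, against 0.70, 1.27 and -0.81. With that score the clock list had a median of 0.17 (adjusted p = 2.25e-05) and the collagen list one of -0.35 (adjusted p = 3.34e-30). Within the 21 and the 9 arrays, 47 and 11 genes passed, Col1a1 differed by -0.77 and -1.07 and Dbp by 0.34 and 0.80, and with the set as a block 214 genes passed. Mitochondrial fatty acid oxidation passed within the 21 arrays (adjusted p = 6.52e-11) and not within the 9 (0.737), and neutrophil markers within the 9 (2.2e-17) and not within the 21 (0.478). On the 9 arrays S100a8 was high in LF day 0 and low in LF day 56, so values within them do not part time from S100a8. Without the arrays with S100a8 above 100, 13 genes passed, the collagen list had an adjusted p = 3.29e-17 and the clock list 0.000208. Both list values used the preset correlation only.

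The comparison of HF day 56 with LF day 0 holds diet, age and time together and is read beside the change on the low fat diet. The amount of bone, cartilage or tendon taken with the muscle is not separable in it either. Genes of mitochondrial fatty acid oxidation rose, by a list median of 0.31, and collagen and matrix genes fell, by a list median of 0.26. Lep rose by 2.28 ± 0.35 (log2, SE; adjusted p = 0.000166) on 10 of 10 arrays, from a mean intensity of 5.7, which is near background, to 27.9. Decr1 rose by 0.59 ± 0.06 (adjusted p = 5.05e-07) and Ech1 by 0.69 ± 0.08 (adjusted p = 8.42e-07), each on 10 of 10 arrays. Col1a1 fell by 0.79 ± 0.15 (adjusted p = 0.00202) on 10 of 10.

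In this comparison 262 genes changed in limma, 129 higher and 133 lower, 63 of them at least 1.5-fold (37 higher, 26 lower). Rises and falls are again ranked only among those of them with a symbol. The largest rises after Lep were those of Tmem45b (2.20), the lipid droplet gene Cidec (1.81), Nnat (1.75), BC048679 (1.68, adjusted p = 3.81e-08), haptoglobin (Hp, 1.66), the immunoglobulin gene Ighg2c (1.44), Sncg (1.37), Rasd2 (1.32) and Sln (1.16, adjusted p = 0.0319), on 9 or 10 of 10 arrays. The largest falls were those of Mettl21e (-1.29), Wif1 (-1.07), the cardiac actin Actc1 (-1.07), Tnc (-0.90), the desaturase Scd2 (-0.87), paraoxonase Pon1 (-0.86), Kera (-0.86), Col1a1, Col1a2 (-0.77) and A930003A15Rik (-0.77), each with an adjusted p of 0.0148 or below and on at least 9 of 10 arrays. Sln, Pon1, A930003A15Rik and Cyp51 lay under a mean intensity of 20 in both groups. Lep, Tmem45b, Ighg2c, Mettl21e, Wif1 and Dhcr7 did in 1 of them, so the sizes of these changes are uncertain as well.

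Mitochondrial fatty acid oxidation rose by a median of 0.31 (adjusted p = 2.76e-29, and 0.00618 with an estimated correlation), with 13 of 23 genes past the test over all genes and 18 adjusted over the list alone, and 10 of 10 HF arrays above the LF day 0 mean. Acadm, Acadl and Eci2 rose by 0.37, 0.38 and 0.28. PPAR targets rose (8 of 23 genes, median 0.31, adjusted p = 2.07e-14, and 0.00618 with an estimated correlation), among them Fbp2 by 0.59. Fatty acid uptake and storage genes rose as well (4 of 20 genes, 10 adjusted over the list alone, adjusted p = 2.23e-09, and 0.0123 with an estimated correlation): the transporters Slc27a1 and Cd36 by 0.76 and 0.41, Plin5 by 0.66 and the triglyceride-forming enzyme Dgat2 by 0.65.

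**Figure D4:**
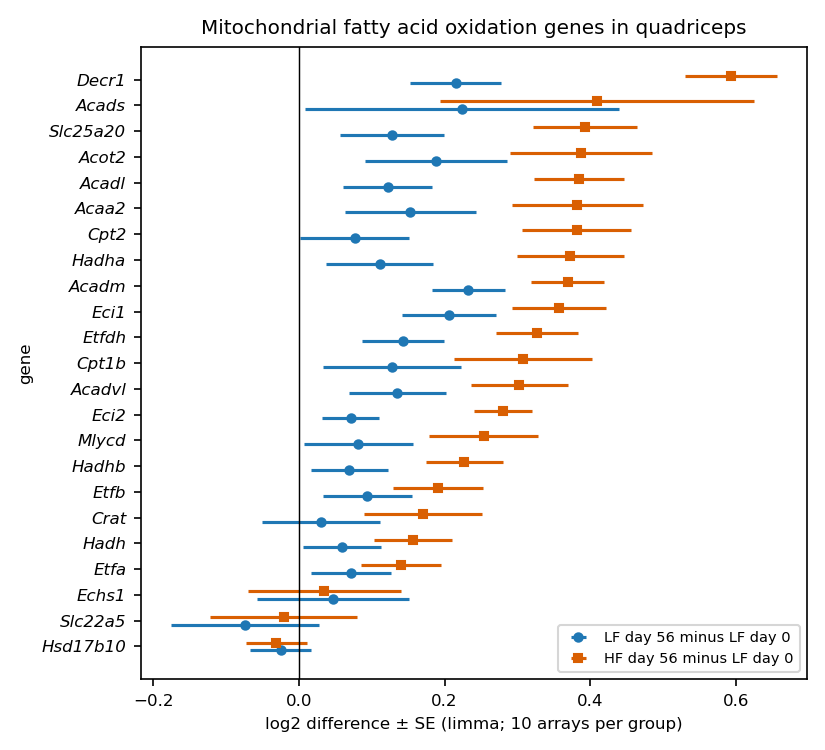
Log2 difference ± SE (limma, 10 arrays per group) of the 23 measured genes of mitochondrial fatty acid oxidation, for LF day 56 (circles) and HF day 56 (squares) against LF day 0. The medians are 0.11 in LF and 0.31 in HF, and Decr1 lies at 0.22 and 0.59.

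Collagen and matrix genes fell (7 of 27 genes, 14 adjusted over the list alone, median -0.26, adjusted p = 6.21e-19, and 0.0425 with an estimated correlation), Col3a1 by 0.48 and Col5a2 by 0.60. Tendon markers fell (4 of 11 genes, adjusted p = 3.92e-12, and 0.00801 with an estimated correlation), with Tnmd at -0.63, Fmod at -0.45 and Thbs4 at -0.42. Clock genes rose (6 of 19, adjusted p = 5.23e-06, and 0.00801 with an estimated correlation), with Cry2 at 0.34, Bhlhe40 at 0.30, Ciart at 0.75 and Dbp at 0.45. Cholesterol synthesis genes fell (2 of 16, adjusted p = 0.0131, and 0.0425 with an estimated correlation), Dhcr7 by 0.40 and Cyp51 by 0.38, while Pmvk (-0.26) and Fdft1 (0.20) did not pass. Fatty acid synthesis genes were lower (2 of 15, adjusted p = 0.00625, but adjusted p = 0.240 with an estimated correlation), with Scd2 and the regulator Srebf1 (-0.45) past the test. Genes of muscle atrophy and autophagy had a median of 0.05 (adjusted p = 0.0219, and adjusted p = 0.0951 with an estimated correlation), with Psmd11 at 0.16 and Cdkn1a at 0.35. Cell cycle genes had a median of -0.16 (adjusted p = 0.0219, and adjusted p = 0.720 with an estimated correlation), with Mcm3 at -0.18. Cdkn1a and Mcm3 lay under a mean intensity of 20 in both groups. The cell cycle list followed S100a8 over the arrays, as described for the change on the low fat diet.

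Adipocyte markers differed in part: 4 of 15 passed over all genes and 7 were higher and 1 lower adjusted over the list alone (median 0.40, adjusted p = 2.71e-07, and adjusted p = 0.0706 with an estimated correlation), among them Lep, Cidec, Adipoq (1.11) and resistin (Retn, 0.82). The mean adipocyte score was -0.46 in LF day 0, 0.03 in LF day 56 and 0.42 in HF day 56. With that score as a covariate 75 genes passed, and 25 of the 44 named genes that had passed did not, among them Lep (1.40, adjusted p = 0.0773), Cidec (0.47), Hp (0.69) and Sln (1.37, adjusted p = 0.102). Lep and Cidec are part of that score, so it takes up some of their difference by construction. Within the 21 arrays 134 genes passed and within the 9 arrays 0 in limma (1323 at an unadjusted p below 0.05). Decr1 differed by 0.62 and 0.53 within these sets, and with the set as a block 384 genes passed. Without the arrays with S100a8 above 100, 6 genes passed, and mitochondrial fatty acid oxidation had an adjusted p = 4.12e-09 with the preset correlation only.

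Of the genes called against LF day 0, 90 were called in the same direction in both day 56 groups (28 higher, 62 lower) and 0 in opposite directions. Independent lists of these sizes would share 1.12. Both comparisons use the same 10 LF day 0 arrays: simulated groups without change shared a median of 0 and at most 9. At an unadjusted p below 0.01 the groups shared 309 genes, and the simulated ones a median of 13.5 and at most 642, with 1 of 100 draws reaching 309. The covariance of the 2 sets of differences was 0.0143, against a simulated median of 0.00502 and a highest of 0.0183, and 1 of 100 draws was as high. With the LF day 0 arrays split into 2 separate groups of 5 a median of 20 was shared (13 to 31). Those splits also called fewer genes, a median of 57 in LF and 113.5 in HF, against 140 and 262. The drop from 90 therefore mixes fewer control arrays with the loss of shared ones. A further 172 genes were called in HF and not in LF, and 50 in LF and not in HF; those numbers do not test the difference between the diets, which the direct comparison does. All 4 genes of the direct diet comparison (BC048679, Decr1, Ech1 and Eci2) were among those called in HF against LF day 0, and BC048679 was also called in LF.

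Mouse-to-mouse spread at day 56 did not differ detectably between the diets. The median within-group variance over genes was 0.0316 in HF and 0.0286 in LF (log2 squared), a ratio of 1.11 (two-sided permutation test, p = 0.336, n = 10 per group).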

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

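The tests of the 9 arrays, of the neutrophil genes and of the fatty acid oxidation genes were chosen only after the results were seen; the regroupings of the arrays were set before their results were seen.

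Regrouping the arrays of each comparison at random, 100 groupings with the real one included, tested whether chance alone gives as much. For the diet, 1 grouping called as many genes as the real 4 (highest other 1). For HF day 56 against LF day 0, 1 called as many as 262 (highest other 26). Only the real grouping reached these counts, which argues against chance as far as 100 groupings can tell. For the diet, 94 of the 99 other groupings called 0 genes. For LF day 56 against LF day 0, 2 groupings called as many as 140. The other one called 212 and had put 0 of the 6 arrays of higher spike-in ratio in its first group, but a grouping with all 6 of them there called 0, so what gave the 212 stays open. With the set of arrays as a block the real grouping called 214. The numbers of lists passing at the preset correlation were 10, 13 and 11 for the diet, LF against day 0 and HF against day 0, and 15, 4 and 13 groupings passed as many (highest other 18, 18 and 16), so chance is not excluded for the first and last. With an estimated correlation, 2, 4 and 7 lists passed, as many as in 1 grouping each, the real one (highest other 1, 2 and 3). The p of mitochondrial fatty acid oxidation was as small in 1 grouping each: 1.01e-21, 8.21e-08 and 7.88e-31, against smallest others of 1e-10, 3.42e-07 and 1.4e-21. For collagens in LF against day 0 it was 2.89e-38 in 1 grouping, against 1.9e-29. The overlap of 90 calls was reached in 1 grouping of the 30 arrays, with a highest other of 0. In each comparison with LF day 0, 95 of the 99 other groupings called 0 genes. An overlap of 0 was thus nearly given in advance, and this test says little about sharing itself.

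A set of 9 arrays stood apart from the other 21 in 3660 genes, with Jph2 at 9.64 against 6.74. Poor RNA in the muscle samples is argued against as the whole cause, since the spike-in control RNAs, which do not come from the muscle, part the same way: the lowest ratio of 5' to 3' signal among the arrays with Jph2 above 8 was -1.27, and the highest of the others -1.49. Diet or day is argued against as well, since each group held 3 of these arrays (exact test, p = 1). All 9 arrays with Jph2 above 8 lay above the gap in the spike-in ratio, so a difference in the labelling of the RNA may account for the pattern. The labels give no labelling batch, so the date or kit behind such a difference stays open.

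Neutrophil genes were high on 17 arrays, with S100a8 above an intensity of 100 (7, 4 and 6 of 10 arrays; exact test over the groups, p = 0.531, which leaves diet or day open, since 10 mice per group show only large differences). Over these arrays Elane, Mpo, Prtn3 and Ctsg, granule genes that granulocyte precursors express, correlated with S100a8 at a median r of 0.74; Elane had r = 0.85 (permutation p = 4e-05, adjusted p = 0.00016 over 20 relations), rho = 0.73 (p = 0.0011) and r = 0.78 without the 2 farthest arrays. The medians of Elane, Mpo, Prtn3 and Ctsg over these arrays were 2.89, 4.15, 3.93 and 2.94 (log2). Each lies under an intensity of 20, so their correlations rest largely on values near background. Ngp, Camp and Ltf, of the same list of precursor genes, had medians of 7.39, 6.03 and 5.26 and r of 0.97, 0.93 and 0.98. Blood alone is argued against for the 8 arrays on which Mpo lay above 20, with a highest log2 value of 8.15 where the 13 arrays of low S100a8 reached 2.0, and stays open for the other 9. Of the mature neutrophil genes, S100a9 (r = 0.99, permutation p = 1e-05, the smallest possible, rho = 0.97, p = 1e-05, and r = 0.99 without the 2 farthest) and Mmp9 (r = 0.81, p = 0.00012, rho = 0.60, p = 0.011, and r = 0.65) followed S100a8 as well, while Csf3r and Cxcr2 stayed under an intensity of 20 (at most 15.8 and 9.8) and decide nothing. Red cell precursor genes were also higher there, with medians for Alas2 of 5.67 against 3.50 and for Ctse of 6.88 against 3.19, which is consistent with some bone marrow in these samples, though Alas2 did not follow S100a8 (r = 0.24, permutation p = 0.36, rho = 0.21, p = 0.42, and r = -0.16 without the 2 farthest).

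Fatty acid oxidation genes were higher in HF than in LF at day 56, by a list median of 0.172. More adipocytes in the HF samples are argued against as the whole cause, since the median was 0.169 with the adipocyte score as a covariate (adjusted p = 2.26e-17). More slow fibres, as read by the slow fibre score, are argued against too. Within groups the list mean rose by 0.07 ± 0.019 (SE) per unit of that score. Its difference of 0.174 would thus need a score higher by 2.49 (1.61 with the slope 2 SE higher). That score was 0.10 in both diet groups (SE of the difference 0.44). A shift among fast fibres was not tested: the 4 type IIA and IIX markers had a mean of 11.50 ± 0.271 (SD) in HF and 11.38 ± 0.263 in LF. Of 10 HF arrays, 8 lay above the LF mean, and the list did not pass (camera, adjusted p = 0.368). The 2 sets of arrays hold the same share of each group, so a shift between them adds nothing to the pooled difference. The median was 0.152 within the 21 arrays (camera, adjusted p = 1.89e-11) and 0.231 within the 9. On the 9, S100a8 was high on replicates 6 and 7 of HF and low on the LF arrays. Pooled differences are weighted means of those within the sets, so these medians are no separate test of labelling. Over the alternatives for this list the adjusted p ran from 1.55e-24 to 0.0284. On the arrays without high S100a8 the list mean ran from 9.93 to 10.11 in HF and from 9.82 to 10.07 in LF. The level of S100a8 was not weighed as a cause. A response of the muscle fibres to the diet is a hypothesis these values leave standing, found and tested on the same data. Whole muscle was measured, so fibres cannot be told apart from other cells, and measuring these genes in isolated fibres would test it.

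Of 435 tests of a gene in a group for a lone high or low array, 24 were positive, where chance at 1 in 20 gives about 22. All values are log2 intensities, with the nearest other array of the group in parentheses. In LF day 0, BC048679 was low on replicate 9 at 6.33 (6.81) and Postn on replicate 7 at 6.43 (6.86). Top2a was high on replicate 2 at 4.74 (3.10). Replicate 6 was high in Cidec at 6.15 (4.99), Nnat at 5.89 (5.04) and Fasn at 7.48 (6.80). In LF day 56, replicate 6 was high in Ucp1 at 7.84 (4.20), Fasn at 9.33 (7.36) and Tmem45b at 6.89 (5.71). Replicate 10 of that group was high in Mss51 at 11.62 (10.42) and Musk at 5.07 (3.99). Replicate 9 was high in Mpo at 7.24 (4.07) and replicate 4 in Lep at 4.15 (3.51). Low values in LF day 56 were Slc51b at 1.54 (1.93) and Cry2 at 7.87 (8.13) on replicate 8, Irs2 at 2.43 (2.83) on replicate 2 and Mccc1 at 8.47 (8.71) on replicate 5. In HF day 56, replicate 2 was high in Elane at 6.07 (3.79) and Ltf at 9.02 (5.33). Replicate 9 was high in Npr3 at 4.52 (3.88) and Slc7a10 at 4.38 (3.47). Lmod3 was high on replicate 7 at 10.21 (10.05) and Ucp1 on replicate 10 at 2.81 (2.20). Dbp was low on replicate 8 at 9.46 (9.73).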

How the results depend on the processing

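The alternatives built on the sets of arrays, the spike-in ratio, the neutrophil score and S100a8 were chosen only after the data were seen. Where a count moved, the cause was not tested, except that leaving out arrays or genes tests fewer of them. The count of 4 diet genes was 0 in a limma fit of only the 2 groups compared (799 genes at an unadjusted p below 0.05), 7 with a trend, 8 with trend and robust priors, and 8 and 9 with filters on low entries. It was 11 with the slow fibre score, 8 with the spike-in ratio and 10 with set, neutrophil and slow fibre scores together. It was 0 in the limma fits of the 21 arrays, of the 9, and without those high in S100a8 (835, 782 and 728 at an unadjusted p below 0.05). Leaving out 1 array gave 2 to 15 genes: 2 without replicate 1, 2, 3, 5, 6, 7, 9 or 10 of LF day 56 or 2, 4, 6 or 8 of HF day 56, and 15, 10, 8 and 11 without replicates 3, 5, 7 and 9 of HF day 56. The 140 genes of LF against day 0 became 214 with the set as a block, 47 and 11 within the 21 and the 9 arrays, 84 with the neutrophil score, 75 with the 3 scores together and 13 without the arrays high in S100a8, and ran from 102 to 155 with 1 array left out. The 262 genes of HF against day 0 became 75 with the adipocyte score, 134 and 0 within the 21 and the 9 arrays (limma; 1323 for the latter at an unadjusted p below 0.05) and 6 without the arrays high in S100a8, and ran from 214 to 271 with 1 left out. At an unadjusted p below 0.01 the 3 counts were 213, 620 and 757.

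Passing lists fell from 10, 13 and 11 to 2, 4 and 7 with an estimated correlation, and to 2, 5 and 9 with fry; without the arrays high in S100a8, 5 passed for LF against day 0. The overlap of 90 genes was 20 with the LF day 0 arrays split into 2 groups of 5, which also called fewer genes (a median of 57 and 113.5). The spread ratio ran from 1.03 to 1.17 with 1 array left out. Of 1850 values of named genes under alternatives, 1755 kept their direction and side of the threshold, 69 no longer passed, 26 newly passed and 0 reversed; the adipocyte score accounted for 33 of the losses. With 1 array left out, 0 of the 4, 32 and 44 named differences that passed moved by over 1.5 times (group means, not a test), and 21, 6 and 2 of those that did not pass did. With the replicate number as a block (replicate block), 1, 104 and 209 genes, 12, 13 and 11 lists and an overlap of 64 were found; arrays of equal number correlated at a mean r of -0.046, -0.004 and 0.001 after removing group means, so the numbers do not pair the mice. Averaging several entries per gene was not run, since each gene has 1. Signal limits the rest: 9631 of the entries tested did not exceed an intensity of 20 on 5 arrays.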

Other observations

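The tests of Lep and of diet against time were chosen only after the results were seen, as were the genes given for single arrays.

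Replicate 6 of LF day 56 was high in some genes of brown fat and of fatty acid synthesis, and not in others. Ucp1, the uncoupling protein of brown fat, read 7.84 (log2), where the other 9 arrays of the group reached 4.20, and Cidea, another brown fat gene, 7.67 against at most 4.08. The following genes of fatty acid synthesis were higher on it than on any of the other 29 arrays: Fasn at 9.33 against at most 7.48, Acly at 7.78 against 6.69, Elovl6 at 4.07 against 2.10 and Thrsp at 8.59 against 7.80. Adipoq, at 10.45, was also the highest of its group (9.39 to 10.21 on the other arrays, and up to 11.40 over all groups), as was the adipocyte score, at 1.16 against at most 0.59. Cpt1b was at 10.03 (9.93 to 10.48 in the group). Of other genes of these kinds, Cox8b was at 12.97, the low end of its group (12.97 to 13.41 on the other arrays). Ppara was at 6.42 (5.34 to 6.76 on the other arrays of the group) and Me1 at 10.80 (up to 11.0 on any other array). Elovl3, at 2.38, Otop1, at 2.66, and Elovl6 lay near background.

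Slow fibre genes varied widely between mice of the same group. The slow fibre score was -0.20 ± 0.80 in LF day 0, 0.10 ± 0.94 in LF day 56 and 0.10 ± 1.03 in HF day 56 (mean and SD, n = 10 each).

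One hypothesis was that the higher level of Lep in HF came from more adipocytes in the muscle samples, which would raise Lep no more than other adipocyte-restricted genes. Lep minus the mean of Adipoq, Retn, Cidec and Adig was -2.29 ± 0.95 (SD) in HF and -3.28 ± 0.36 in LF at day 56, a difference of 0.99 (two-sided permutation test, p = 0.00476), while the other 4 genes differed by a mean of 0.59. Within the 21 arrays the difference was 1.39 and within the 9 it was 0.06. Lep did not exceed an intensity of 17.7 on any LF day 56 array and ranged from 8.5 to 186.7 in HF, so it lay near background in LF, and more adipocytes cannot be told apart from more Lep per adipocyte.

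Another hypothesis was that the high fat diet adds, over all genes, to the change seen over time on the low fat diet. Across the 6844 genes with signal, the covariance of the diet and time differences was -0.00919, where simulated groups without effects gave a median of -0.00621 (-0.0238 to 0.00321), negative because both differences use the LF day 56 arrays. Of 100 simulated draws 69 were as high, so the test showed no such general addition.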
